A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

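The data are lists of called regions from calibrated ChIP-seq in fission yeast (Schizosaccharomyces pombe). Cells without a tag, with Pli1-12Pk or with Nse2-12Pk were grown in rich medium, mixed with budding yeast cells as a calibrator, crosslinked and precipitated with an antibody against the Pk tag. Per the labels, signal was taken as the ratio of ChIP to input, normalised to the calibrator. The submitters' processing notes name cutadapt, Bowtie2, SAMtools and MACS3 and the genome build sacCer3, which is that of the calibrator. They give no versions or roles. Per the file headers, reads mapped uniquely to S. pombe were used and regions were called on a p-value track. Each list came from 1 library, not from pooled samples.

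The unit is the authors' deposited score, a whole number per region. Its scale, the threshold for a call, the calibration factors and the read depths are not given in the sources used here. The columns for fold enrichment, p and q (3 columns) hold 0 for every region. The planned ranking by fold enrichment was therefore replaced by ranking on the score within a list, and scores were not compared between lists. The fission yeast build is not stated, but the sequence names and versions of the lists match the ASM294v3 reference, and no region ran past the end of a chromosome. Positions are given counting from 1.

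Samples were grouped by strain and by ChIP or input, as their titles state. The 3 input samples were not analysed here on their own. The comparisons, the locus classes, the gene lists and the rule for naming loci were fixed before the data were examined. The rule named the 15 Pli1 and 15 Nse2 regions ranked highest among those outside untagged peaks, the 10 highest untagged peaks, the 10 highest Pli1 regions that touched Nse2, the genes of any class with 5 or fewer members touched, and pli1 and nse2. A region took the name of the gene at its summit, or else of the nearest gene. Where genes overlap at a summit, the text gives 1 of them. The analyses of summits in locus classes and in untagged peaks, and of gaps between regions, were added after the tagged lists were seen to cover nearly the whole genome.

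Regions were compared by overlap of at least 1 bp, with code written for this purpose in Python 3.11.15 with NumPy 2.4.6 in place of the planned bedtools. The code was tested on simulated data, where it recovered 200 of 200 peaks planted on tRNA genes among 3535. Exact binomial intervals came from SciPy 1.17.1 and figures from Matplotlib 3.10.9. Each list was set against 1000 random placements that kept the length and chromosome of every region. Summits of tagged regions were set against positions drawn evenly within their own region, and untagged summits against positions drawn along their chromosome. The median and the central 95% of the draws describe the placements and are not a test. For AT content of untagged peaks and of random intergenic stretches, 200 draws were used. The class ratios with merged regions or with untagged scores of at least 100 also rest on 200 draws. The GC content at ura4 was set against 2000 windows.

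Locus classes came from the annotation: tRNA, 5S, large rRNA (rDNA), snRNA and snoRNA and long non-coding RNA genes, Tf2 retrotransposons, LTRs, and ribosomal protein genes by symbol or product. The rDNA-bearing ends are the outer 30 kb at each end of chromosome III. Subtelomeres are the outer 100 kb of each chromosome arm, without the rDNA on chromosome III, and the mating-type region spans the annotated mat genes. The annotation has no centromere features, so the PomBase centromere intervals were used. Gene lists covered histones, glycolysis and fermentation, translation factors, heat shock and stress, plasma membrane and nutrient transport, iron and phosphate, one-carbon, methionine and thiamine metabolism, the SUMO pathway, the Smc5/6 complex, other RNA polymerase III genes, fork barrier and termination factors, marker genes and subtelomeric tlh genes. Symbols were matched by name or synonym. The symbol aap1 matched a synonym of ape4, an aminopeptidase gene, and 2 of 4 tlh genes were found. A summit was assigned to a class within 200 bp of a member. Repeated sequence was mapped as 50-mers that occur more than once in the genome on either strand. AT content was taken over 500 bp around each summit. The B-box was searched as its consensus on either strand within 150 bp of a summit, and the HindIII fragment around ura4 was taken from the enzyme's sites in the reference sequence. The alternatives changed the overlap rule, the merging of neighbouring regions, the length of the untagged list, the class assignment, the random placement, the window sizes and the gene set.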

Results

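The series mapped 2 SUMO ligases of fission yeast on chromatin. Pli1 is a PIAS-family ligase that attaches the modifier SUMO to nuclear proteins, and Nse2 is the ligase subunit of the Smc5/6 complex, which acts in DNA repair. Both carried a Pk epitope tag (Pli1-12Pk and Nse2-12Pk), and DNA was recovered with an antibody against Pk from these strains and from a strain with no tag. The 6 samples were 1 ChIP library and 1 input for each of the 3 strains, from growing cultures mixed with budding yeast cells as a calibrator. The values are the authors' lists of called regions, each region with a start, an end, a summit (the position of its highest signal) and a score. The read depth behind each list is not given in the sources used here. With 1 ChIP library per strain there are no replicates, so no test was made between strains, and the difference between Pli1 and Nse2 was not tested. Shares are given with exact (Clopper-Pearson) 95% intervals, which cover counting error only, and random placements describe what position alone gives.

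The lists differed first in how much of the genome they held. The untagged list had 3535 peaks with a median length of 559 bp, and together they covered 18.7% of the genome. The Pli1 list had 299 regions with a median length of 28719 bp and covered 99.3%. The Nse2 list had 62 regions with a median length of 69235 bp, the longest of them 1548631 bp, and covered 99.8%. Regions of at least 10 kb held 97% of the genome in the Pli1 list and 99.3% in the Nse2 list. A region of a tagged list therefore names a long stretch, and the summit inside it is the position with finer detail. Scores ran from 18 to 12828 in the untagged list (median 129), from 85 to 28692 for Pli1 (median 2537) and from 97 to 41291 for Nse2 (median 11305). Their scale is not stated, so they rank regions within a list and were not compared between lists.

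The untagged list shows what the antibody and the chromatin gave without the tag. Its highest scores fell in the ribosomal RNA genes at both ends of chromosome III, which code for the RNA of the ribosome. The 28S gene SPRRNA.49 held the top score (12828, summit at position 2444388), and the 18S gene SPRRNA.44 (7115) and the 28S genes SPRRNA.48 (6247) and SPRRNA.47 (5819) came after it and a further SPRRNA.49 peak (7758). The other peaks among the 10 highest were at the 18S genes SPRRNA.43 (3331) and SPRRNA.46 (1824), at ssa2 (2584), which codes for an Hsp70 chaperone, at the ribosomal protein gene rpp0 (1636), and at the non-coding RNA SPNCRNA.7192 in centromere 3 (1306). Ribosomal protein genes were touched by 92 untagged peaks, against a median of 55 in 1000 random placements (central 95% of placements, 41 to 70). Their median score was 372, against 127 for the other peaks. Tf2 retrotransposons were touched by 41 peaks, against 17 (9 to 26). Few peaks touched small RNA genes. For tRNA genes the count was 6, against 31 at random (21 to 42). It was 3 against 8 (3 to 14) for 5S rRNA genes, 1 against 14 (8 to 22) for snRNA and snoRNA genes, and 0 against 62 (48 to 79) for the long terminal repeats (LTRs) of retrotransposons. Counts lay inside the random range for centromeres (41, against 42), subtelomeres (150, against 172), the rDNA (7, against 7) and the mating-type region (7, against 5), and below it for long non-coding RNA genes (2259, against 2427.5). The Tf2 count fell to 16 peaks, 1.10 times the random mean, when peaks within 500 bp were merged.

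Seen from the genes, the untagged peaks touched most members of several metabolic and housekeeping lists. All 17 genes of glycolysis and fermentation were touched, among them adh1 and eno101, which code for alcohol dehydrogenase and enolase. All 11 translation factor genes were touched too, as were 14 of 16 heat shock and stress genes, 11 of 12 genes of plasma membrane and nutrient transport, 8 of 9 iron and phosphate responsive genes and 8 of 10 genes of one-carbon, methionine and thiamine metabolism. By number of peaks touching them these lists lay within the random range or at its upper end, with 19 for glycolysis (5 to 19), 14 for translation factors (3 to 15), 20 for heat shock (7 to 20), 14 for transport (5 to 17), 11 for iron and phosphate (2 to 12) and 12 for one-carbon, methionine and thiamine genes (3 to 13). By summit within 200 bp, the counts of 19 for glycolysis (5 to 17) and 20 for heat shock (6 to 19) were above it. Ribosomal protein genes followed with 88 of 142 (62.0%, interval 53.5 to 70.0%), against 2774 of all 5113 protein-coding genes (54.3%). Of the 11 histone genes, 5 were touched (hht1, hht2, hht3, htb1 and pht1). In the SUMO pathway the count was 7 of 14, including pmt3, which codes for SUMO itself, and cdc48. In the Smc5/6 complex it was 2 of 8 (smc6 and nse5), and among replication fork barrier and termination factors 3 of 6 (sap1, rtf2 and swi1). Among RNA genes, 13 of 171 tRNA genes were touched (8 of the 28 in centromeres), 3 of 36 5S genes (SPRRNA.39, SPRRNA.26 and SPRRNA.06), 1 of 72 snRNA and snoRNA genes (snoU14), and 2 of 4 other RNA polymerase III genes (rrk1 and mrp1, the RNAs of RNase P and RNase MRP). All 13 Tf2 elements, both subtelomeric helicase genes found (tlh1 and tlh2), 2312 of 7168 long non-coding RNA genes, 6 of 11 large rRNA genes and 0 of 238 LTRs completed the lists. The tagged lists touched every member of these groups except some LTRs (233 of 238 touched in the Pli1 list) and, in the Nse2 list, 1 long non-coding RNA gene. No list had a peak on the mitochondrial genome.

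The marker gene ura4, which codes for an enzyme of uracil synthesis, lay outside all 3 lists. Of the 6 marker genes of laboratory strains, the untagged list touched 5 (leu1, ade6, his3, arg3 and lys1), and each tagged list also touched 5, with ura4 left out. The gene ura4 occupies positions 115589 to 116625 of chromosome III. Around it the Pli1 list had a gap of 1962 bp (115274 to 117235) and the Nse2 list a gap of 1861 bp (115307 to 117167). The nearest untagged peak was 2849 bp away.

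**Figure D1:**
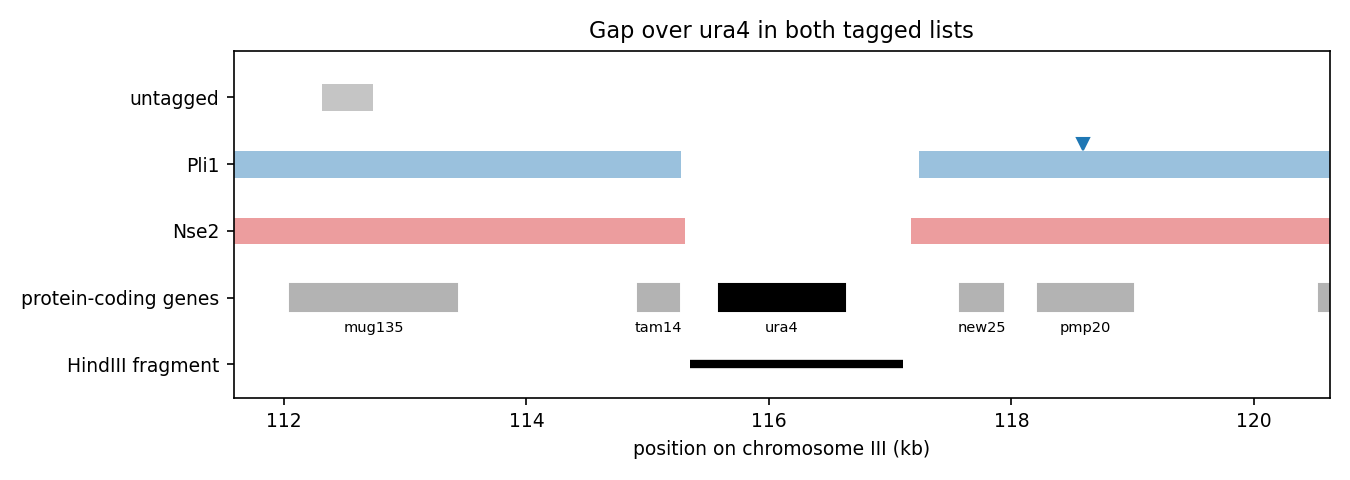
Called regions of the untagged, Pli1 and Nse2 lists around ura4, against position on chromosome III in kb, with protein-coding genes, the HindIII fragment of the reference sequence that holds ura4, and a triangle at the Pli1 summit. Both tagged lists leave the whole of ura4 uncalled, over 1962 bp for Pli1 and 1861 bp for Nse2.

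Comparing the Pli1 list with the untagged list asks which sites were called with the tag alone. Regions in ribosomal RNA genes led the Pli1 regions that touched no untagged peak. The highest scores were in the 28S genes SPRRNA.48 (20522, summit at position 17170 of chromosome III), SPRRNA.47 (19930, position 6303) and SPRRNA.49 (17666, position 2446956). These genes were not free of untagged signal: elsewhere in them lay untagged peaks with scores up to 6247, 5819 and 12828 in the same order. The Pli1 regions named here lay beside gaps inside the genes, such as 6487 to 7377 in SPRRNA.47. SPBTRNAILE.06, a tRNA-Ile gene in centromere 2, lay 26 bp from the summit of a region with a score of 7950 (chromosome II, 1616797 to 1629529). That region ranked below regions at SPRRNA.46, SPNCRNA.1094 and SPRRNA.45 that are given next. In all, 252 of 299 Pli1 regions touched an untagged peak, against a random median of 268 (260 to 275). The other 47 regions (15.7%, interval 11.8 to 20.3%) touched none, against a median of 31 in random placements. These regions were short, with a median of 1135 bp against 35682 bp for the others, and 9 of them lay in the rDNA-bearing ends of chromosome III. Of the 15 with the highest scores, 7 others were also at chromosome ends: SPRRNA.46 (13441 and 6085), SPRRNA.45 (8191), SPNCRNA.1094 (9289), SPNCRNA.6665 (6688) and SPNCRNA.6672 (6016) on chromosome III, and SPNCRNA.6662 (4167) at the right end of chromosome II. The remaining 4 were at SPAC17A2.11 (6581), the ribosomal protein gene rpl3703 (1723), mix17 (1455) and SPAPB15E9.06 (1351). With regions within 500 bp merged first, 9 of 30 Pli1 regions touched no untagged peak, and 131 of 299 Pli1 summits lay outside untagged peaks. The count of regions was 39 of 285 without the rDNA, 161 against an untagged list of equal length and 295 when at least 50% of a region had to be covered. No random placement was run for the count without the rDNA.

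The same comparison for Nse2 also led with ribosomal RNA genes. The highest scores outside untagged peaks were in the 28S genes SPRRNA.47 (28761, position 6301), SPRRNA.48 (27885, position 17170) and SPRRNA.49 (23590, position 2446953), then at SPRRNA.46 (14656 and 8225), SPNCRNA.1094 (11713), SPRRNA.45 (9848) and SPRRNA.44 (6346). As for Pli1, the 28S genes held untagged peaks elsewhere in the gene, so they were not free of untagged signal. Away from the rDNA, the region with the highest score was at SPNCRNA.6662 (5636), at the right end of chromosome II. It was followed by SPBC32H8.15 (5402), SPNCRNA.1425 (1364), SPNCRNA.944 (852), SPBPJ4664.02 (841), SPBC16E9.20 (838) and a region beside utp24, an rRNA processing gene (682). In all, 45 of 62 Nse2 regions touched an untagged peak, against a random median of 52 (48 to 56). The other 17 regions (27.4%, interval 16.9 to 40.2%) touched none, against a random median of 10, and 9 of them were in the rDNA-bearing ends. Their median length was 954 bp, against 159171 bp for the others. The count was 9 of 51 without the rDNA, 6 of 17 with regions within 500 bp merged, 36 against an untagged list of equal length, and 62 when at least 50% of a region had to be covered. Here too, no random placement was run without the rDNA.

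The position of the summits related the tagged lists to the untagged list more closely than the regions did. Away from the rDNA, 6 of the 7 highest Nse2 scores had their summit inside an untagged peak: adh1 (41291), thi2 (34808), a thiamine synthesis gene, SPNCRNA.7192 in centromere 3 (31404), eno101 (30303), ssa2 (29073) and tef103 (28833), a translation elongation factor gene. The exception was rpp202 (37798), an acidic ribosomal protein gene in the mating-type region (chromosome II, position 2128221). These loci were chosen after their values were seen. Of the 62 Nse2 summits, 41 lay inside an untagged peak (66.1%, interval 53.0 to 77.7%), against 14.5% for positions drawn at random within the same regions. Of the 299 Pli1 summits, 168 did (56.2%, interval 50.4 to 61.9%), against 17.4%. In regions of at least 10 kb the share was 92.3% for Nse2 (36 of 39; random median 7) and 63.8% for Pli1 (136 of 213; random median 40). In shorter regions it was 21.7% for Nse2 (5 of 23; random median 2, 0 to 4) and 37.2% for Pli1 (32 of 86; random median 12).

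Comparing Pli1 with Nse2 asks whether both ligases were at the same sites. The 10 highest Pli1 scores among regions that touched Nse2 were in the 28S genes SPRRNA.48 (28692, 22584 and 20522), SPRRNA.47 (28554, 21798 and 19930) and SPRRNA.49 (25982, 22274 and 17666), and at the non-coding RNA SPNCRNA.954 (27867, chromosome I, position 3991644). SPNCRNA.954 lay inside an Nse2 region of 1392515 bp, with the nearest Nse2 summit 114227 bp away. All 299 Pli1 regions touched an Nse2 region and 60 of 62 Nse2 regions touched a Pli1 region, the exceptions being regions of 348 bp in SPRRNA.44 and 448 bp near SPRRNA.46. Random placements gave 299 and 62, since each list covered nearly the whole genome, so these counts carry no detail. Among regions outside untagged peaks, 15 of 47 Pli1 regions touched 1 of the 17 Nse2 regions and 13 of 17 Nse2 regions touched a Pli1 region. No random placement was run for these 2 counts. In each list 9 of these regions lay in the rDNA-bearing ends, and 55 of 65 Nse2 gaps touched a Pli1 gap. The counts alone therefore do not show shared binding. By summit, 40 of 62 Nse2 summits (64.5%, interval 51.3 to 76.3%) lay within 500 bp of a Pli1 summit, against a random median of 12. Of these 40, 10 were in the rDNA-bearing ends, 21 were elsewhere inside untagged peaks, such as adh1 (58 bp apart), eno101 (29 bp), ssa2 (69 bp) and snoU14 (22 bp), and 9 were elsewhere outside untagged peaks. Of these 9, 6 were in Nse2 regions of 577 to 1245 bp (SPNCRNA.944, SPNCRNA.1425, SPNCRNA.6662, SPBC16E9.20 and SPBPJ4664.02, which held 2), where the length of the region leaves little room for distance. The other 3 were at the centromeric tRNA gene SPBTRNAILE.07 (7 bp), the ribosomal protein gene rpp103 (16 bp) and SPNCRNA.7221 (55 bp). In Nse2 regions of at least 10 kb, 21 of 39 summits (53.8%, interval 37.2 to 69.9%) lay within 500 bp of a Pli1 summit, against a random median of 1.

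The locus classes ask whether Pli1 was at the fragile loci named in the title of the series, and by summit Pli1 was above random at tRNA genes, which were mostly free of untagged peaks, and at several groups of protein-coding genes, which mostly were not. Of the 299 Pli1 summits, 19 lay within 200 bp of a tRNA gene (6.35%, interval 3.87 to 9.75%), against a median of 2 for random positions in the same regions (0 to 5). Of these 19, 16 lay outside untagged peaks, 7 fell inside the tRNA gene, and the farthest was 28 bp away. Untagged summits near tRNA genes numbered 7, against 21 at random (12 to 30). The 4 tRNA-Ile genes in and beside centromere 2 each had a Pli1 summit: SPBTRNAILE.05 (score 7149), SPBTRNAILE.06 (7950), SPBTRNAILE.07 (6567) and SPBTRNAILE.08 (7179), with distances of 28, 26, 19 and 26 bp. Each summit lay between its tRNA-Ile gene and a tRNA-Ala gene: SPBTRNAALA.08, SPBTRNAALA.09, SPBTRNAALA.10 and SPBTRNAALA.11 in the same order. The summits therefore cannot be assigned to the tRNA-Ile genes alone. SPBTRNAILE.05, SPBTRNAILE.07 and SPBTRNAILE.08 were chosen after their values were seen. All 4 summits lay in repeated sequence, with 331, 349, 349 and 329 repeated 50-mers within 150 bp, so they may not be 4 separate sites. Other RNA genes were also near Pli1 summits. There were 5 summits at 5S genes (0 to 2 at random; SPRRNA.15, SPRRNA.28, SPRRNA.39, SPRRNA.34 and SPRRNA.06) and 4 at snRNA and snoRNA genes (0 to 3; snoU14, snoR69b, snu2 and the pair snoZ3 and snoZ4). Ribosomal protein genes had 33 (11%, interval 7.72 to 15.1%), against 4 (1 to 8), of which 9 lay outside untagged peaks. Translation factor genes had 7 (0 to 2 at random), with 1 outside untagged peaks, and glycolysis genes 5 (0 to 2; tpi1, eno101, pyk1, pdc101 and adh1), with 0 outside. As ratios to the random mean these were 12.8 and 12.5, beside 11 for tRNA genes. The ratio for tRNA genes was 25.8 with a window of 50 bp and 6.02 with 500 bp. Those windows were not run for translation factor and glycolysis genes, so the order of the classes rests on the 200 bp window. Heat shock genes had 4 (0 to 3; hsp90, ssa1, ssa2 and sks2), histone genes 2 (0 to 1; hhf1 and htb1), and LTRs 0, against 3 (1 to 7).

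By region rather than by summit, Pli1 regions touched centromeres 15 times, against a random median of 6 (2 to 12), and the rDNA 14 times, against 1 (0 to 3). Their counts were 18 for subtelomeres (15 at random; 8 to 23), 1 for the mating-type region (1; 0 to 4), 78 for tRNA genes (83; 71 to 96), 13 for Tf2 elements (12; 6 to 20), 84 for ribosomal protein genes (90; 75 to 102), 281 for long non-coding RNA genes (288; 281 to 293) and 101 for LTRs (104; 90 to 117). By summit, long non-coding RNA genes had 160, below random (189; 174 to 202). The list covered nearly the whole genome, so a domain's region count rises with the gaps that cut it and does not show binding. Pli1 gaps touched centromeres 12 times, against 3 at random (0 to 7), and the rDNA 13 times, against 0 (0 to 2). Rotating the whole list took the rDNA ratio to the random mean from 16.5 to 7.69. Scores of Pli1 regions were highest in the rDNA, with a median of 20226 against 2426 for the other regions. Untagged scores were also higher in the rDNA, with a median of 6247 against 129 for the other peaks, so this was not particular to Pli1. For classes spread along the chromosomes, long regions touch more features, so their scores were not compared by class. With regions within 500 bp merged, the centromere count was 3, or 0.765 times the random mean, and the subtelomere count was 10, or 3.77 times. A count of 3 is 1 region per centromere, the lowest possible for a list that touches all 3, so it says little.

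**Figure D2:**
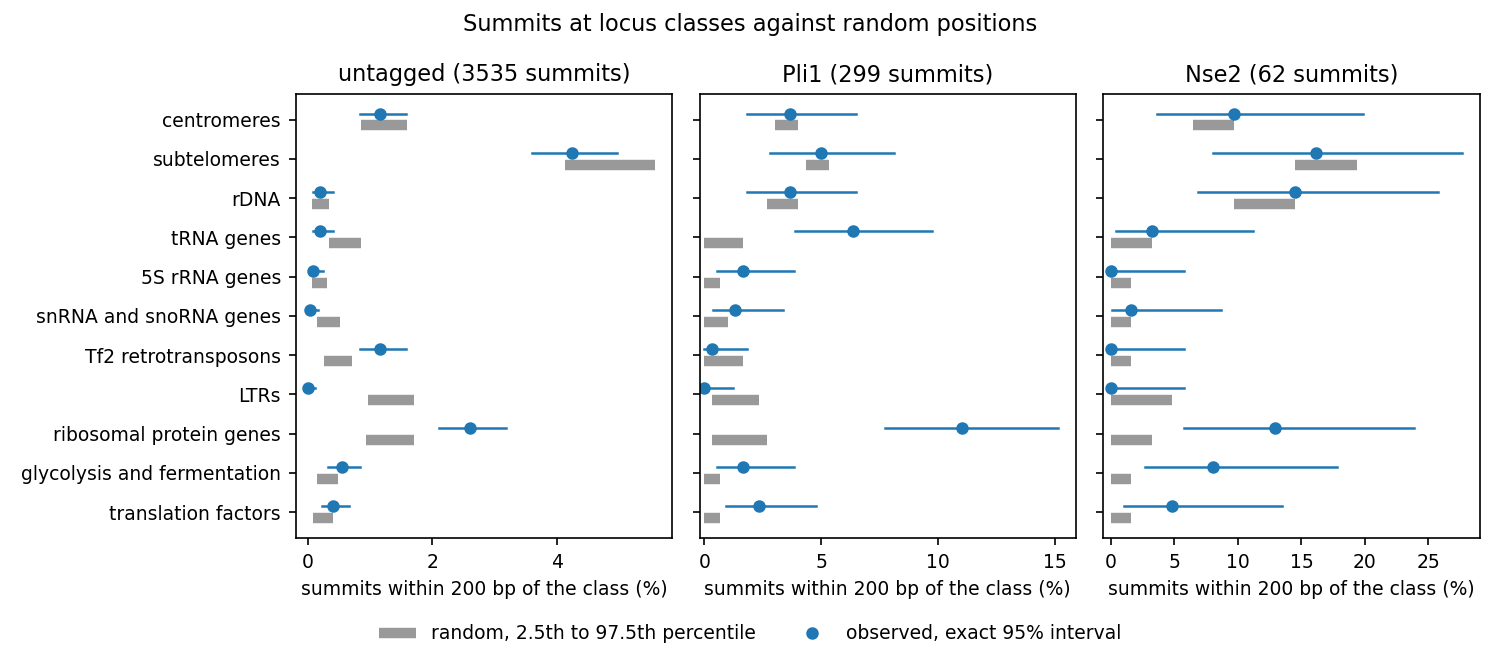
Share of summits within 200 bp of each locus class, in percent, for the untagged, Pli1 and Nse2 lists; points are observed shares with exact 95% intervals and grey bars hold the central 95% of 1000 random draws. Pli1 summits stand above the random range at tRNA genes (6.35%) and ribosomal protein genes (11%), while untagged summits lie below it at tRNA genes; for centromeres, subtelomeres and the rDNA, tagged summits were redrawn within the same regions, which keeps the random range near the observed share.

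**Figure D3:**
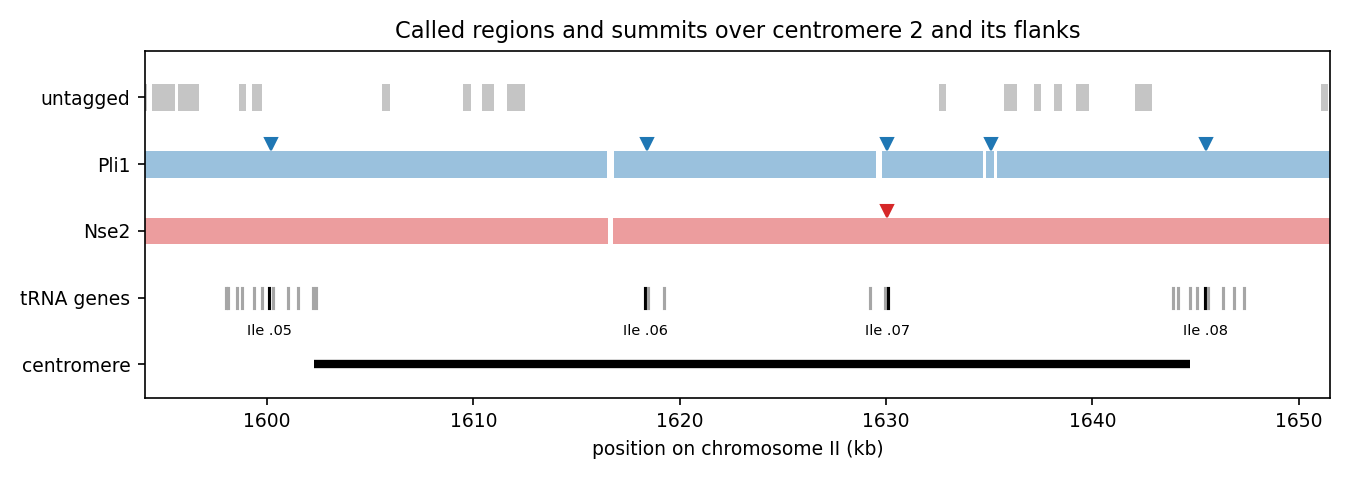
Called regions over centromere 2 and its flanks against position on chromosome II in kb, with triangles at the Pli1 and Nse2 summits, vertical bars at tRNA genes and the tRNA-Ile genes in black. The 4 tRNA-Ile genes each lie within 28 bp of a Pli1 summit, and SPBTRNAILE.07 also has the Nse2 summit. Each of these summits lies between a tRNA-Ile gene and a tRNA-Ala gene. All 4 Pli1 summits lie in repeated sequence and may not be separate sites.

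For Nse2, summits were above random at ribosomal protein genes and at several groups that also carried untagged peaks. Ribosomal protein genes had 8 of 62 summits (12.9%, interval 5.74 to 23.9%), against a random median of 0 (0 to 2): rpp202, rps1001, rps1401, rps1402, rpp103, rpl1802, rpl22 and rpl35, of which rpp202 and rpp103 were outside untagged peaks. Glycolysis genes had 5 (adh1, eno101, pyk1, pdc101 and fba1), translation factor genes 3 (tef101, tef103 and tef5), heat shock genes 2 (ssa2 and mcp60) and one-carbon, methionine and thiamine genes 2 (met26 and thi2), against 0 to 1 at random for each group, and all of these summits lay inside untagged peaks. There were 2 summits near tRNA genes (3.23%, interval 0.393 to 11.2%; 0 to 2 at random), at SPBTRNAILE.07 and SPCTRNAARG.12. Both genes are in centromeres, and for centromeric tRNA genes alone the count of 2 stood against a random range of 0 to 1. The summit at SPBTRNAILE.07 lay outside untagged peaks and that at SPCTRNAARG.12 inside one. Both summits had repeated sequence within 150 bp, and SPBTRNAALA.10 and SPCTRNAASP.06 also lay within 200 bp of an Nse2 summit. By region, Nse2 touched subtelomeres 15 times (4 at random; 1 to 8), centromeres 10 times (4; 1 to 8) and the rDNA 11 times (0; 0 to 2), where the median score was 23590 against 10399 elsewhere. Its counts were 30 for tRNA genes (30; 25 to 34), 32 for ribosomal protein genes (31; 27 to 36), 9 for Tf2 elements (9; 5 to 13), 32 for LTRs (33; 29 to 38), 20 for 5S genes (19; 14 to 24) and 50 for long non-coding RNA genes, below random (58; 54 to 61). By summit, long non-coding RNA genes had 24, also below (33; 27 to 39). As for Pli1, a domain's region count rises with the gaps that cut it and does not show binding. Nse2 gaps touched subtelomeres 13 times, against 4 at random (1 to 8), centromeres 7 times, against 1 (0 to 3), and the rDNA 11 times, against 0 (0 to 1). Rotating the whole list took the ratio from 3.88 to 2.28 in subtelomeres and from 32.4 to 8.32 in the rDNA. Untagged scores were also higher in the rDNA (median 6247, against 129 elsewhere). With regions within 500 bp merged, the centromere count was 3, or 0.770 times the random mean, again 1 region per centromere and the lowest count possible.

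The tagged genes were checked for a signal of their own. The gene pli1 (SPAC1687.05, chromosome I, 908696 to 911854) held an untagged peak with a score of 90. In the Pli1 list it lay in a region of 45863 bp with a score of 2569 and a summit 9948 bp away. The gene nse2 (SPAC16A10.06c, chromosome I, 3089494 to 3090728) held no untagged peak. In the Nse2 list it lay in a region of 1345222 bp with a score of 12395, and that region's summit was 69693 bp away.

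The last comparison asks which gene neighbourhood the summits occupied. Untagged summits were inside protein-coding genes in 97.3% of cases (interval 96.7 to 97.8%), against 76.7% for random positions, and 0.453% were between divergent genes, where promoters meet, against 10.0%. Pli1 summits were inside protein-coding genes in 66.9% of cases (interval 61.2 to 72.2%), against 65.9% (61.5 to 69.9%) for random positions in the same regions, and between divergent genes in 8.36%, below the random range of 9.03 to 14.7%. With RNA genes other than long non-coding RNA genes added, 73.9% of Pli1 summits were inside genes, above the random range of 64.5 to 72.9%. Nse2 summits were inside protein-coding genes in 62.9% of cases (interval 49.7 to 74.8%), against 50.0% (40.3 to 56.5%), and between divergent genes in 3.23%, against 9.68% (4.84 to 16.1%). All 3 kinds of summit sat in DNA with less A and T than the genome, whose mean was 63.9%. Over 500 bp the mean AT content was 58.4% (SD 3.22, 3535 summits) in the untagged list, 59.6% (SD 5.11, 299 summits) for Pli1 and 56.9% (SD 5.43, 62 summits) for Nse2.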

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

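The alternatives with scores of at least 100 (untagged) or 1000 (tagged), the 50 bp and 500 bp windows, RNA genes other than long non-coding RNA genes, regions of at least 10 kb, the 1000 highest untagged scores, summits or gaps without the rDNA and scores by summit were chosen after seeing the data, as was the choice of classes to lead with. Of 160 alternatives over 56 results, 108 kept the value within its interval or a count within 1.5 times and 52 moved it. The number that went to the opposite side of the random range was 0. Such a change could occur only for class counts and AT content whose main value lay outside its random range. For the other results the 0 was fixed in advance and says nothing. Ratios near or above 1 crossed 1 as given here. Thresholds on q of at least 10 and on fold of at least 2 were not run, because those columns hold 0. No paired analysis was possible because there is 1 library per strain. Pli1 regions outside untagged peaks, 47 of 299, were 295 when at least 50% of the region had to be covered, 131 by summit, 161 against an untagged list of equal length and 9 of 30 with regions within 500 bp merged. For Nse2 the count of 17 of 62 was 62 by 50% coverage, 36 against an untagged list of equal length, 6 of 17 with merging and 9 of 51 without the rDNA. Sharing with merged regions was 16 of 17 for Nse2 and 30 of 30 for Pli1, from construction. With the Pli1 list cut to as many top scores as the Nse2 list holds, 40 of 62 Nse2 regions touched Pli1, and no random placement was run for that count. The ratios to the random mean that follow compare counts in classes. With merging, Tf2 elements in the untagged list went from 2.40 to 1.10, and centromeres from 2.27 to 0.765 for Pli1 and from 2.21 to 0.770 for Nse2. The merged tagged lists touched each centromere with 1 region, the lowest count possible, so these centromere ratios say little. Assigning by summit also set the random positions within the same regions, which by construction holds ratios near 1 for wide domains and says nothing on the region counts there: 1.11 for centromeres and 1.17 for the rDNA with Pli1, 0.972 for subtelomeres and 1.24 for the rDNA with Nse2. For short features it gave Pli1 11 for tRNA genes and 8.53 for ribosomal protein genes, and Nse2 4.71 for tRNA genes (2 summits) and 14 for ribosomal protein genes. Rotating whole lists gave 7.69 for Pli1 in the rDNA, and for Nse2 8.32 in the rDNA and 2.28 in subtelomeres. Untagged peaks scoring at least 100 gave 2.35 for ribosomal protein genes. Windows of 50 bp and 500 bp gave 25.8 and 6.02 for Pli1 summits at tRNA genes (19 and 20 summits), and 2.71 and 1.56 for untagged summits at ribosomal protein genes. With 200 bp added to each side, 7 of 238 LTRs were touched by untagged peaks. With all RNA genes counted, 99.5% of untagged, 91.0% of Pli1 and 91.9% of Nse2 summits lay inside genes, and without long non-coding RNA genes 97.8%, 73.9% and 79.0%. Over 200 bp, AT content at summits was 56.1%, 55.7% and 52.8% in the same order. Pli1 summits inside untagged peaks were 63.8% in regions of at least 10 kb and 38.8% against the 1000 highest untagged scores, and Nse2 summits were 92.3% in such regions. Of 49 alternatives for classes not led with, 10 left their interval, 4 of them above 1 and 6 below: for Pli1, 3.77 in subtelomeres with merging, and by summit 9.40 at 5S genes, 0.468 at Tf2 elements, 0 at LTRs and 0 in the mating-type region; for Nse2 by summit, 11 in the mating-type region (1 summit) and 0 at 5S genes, Tf2 elements and LTRs; and 1.36 in centromeres for untagged peaks scoring at least 100. Apart from the merging and the summit null, the causes were not tested. The depth behind each list is unknown, so what depth limits could not be stated.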

Other observations

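The gaps and the summits outside untagged peaks were examined after the lists were seen, and the tests of calibration or depth, of low GC content and of background over tRNA genes were chosen only after the result they concern was seen. The Pli1 list left 302 gaps, 93055 bp in all, with a median of 218 bp, and the Nse2 list left 65, 25435 bp in all, with a median of 262 bp. Of the Nse2 gaps, 55 touched a Pli1 gap, against a random median of 1. Pli1 gaps fell mostly between protein-coding genes: 135 touched a stretch between divergent genes, where promoters lie (39 at random), 106 a stretch between tandem genes (47), and 73 a protein-coding gene (252). Long non-coding RNA genes were touched by 176 Pli1 gaps, within the random range (178; 161 to 194), and by 28 Nse2 gaps, below it (40; 32 to 47). Nse2 gaps lay within the random range at divergent stretches (15, against 4 to 15) and tandem stretches (16, against 5.98 to 17). They were above it at convergent stretches (10, against 0 to 7) and below it at protein-coding genes (15, against 48 to 59). LTRs were in 19 Pli1 gaps (3 at random; 1 to 8) and in 1 Nse2 gap (1; 0 to 3), and tRNA genes in 0 gaps of either list (for Pli1, 1 at random; 0 to 4). Within the 28S genes the longer Pli1 gap recurred at like offsets from the 5' end, 2165 to 3055 bp in SPRRNA.47, 2166 to 3054 bp in SPRRNA.48 and 2252 to 3084 bp in SPRRNA.49. In the 18S genes the Pli1 gaps differed between copies, with 1 gap from 1 to 1336 bp in SPRRNA.43 but 2 gaps in SPRRNA.46 (211 to 575 and 869 to 1377 bp). Gaps avoided the untagged peaks, which were touched by 1 of 302 Pli1 gaps (80 at random) and by 0 of 65 Nse2 gaps (19 at random).

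Several of the highest Pli1 summits away from the rDNA lay outside untagged peaks and in sequence with 0 repeated 50-mers within 150 bp. They were chosen after their values were seen. Besides SPNCRNA.954 (score 27867), they were at SPAC56F8.13 (16223), at SPNCRNA.1389, which lies 1011 bp from the spermidine transporter gene mfs3 (13637), at rgp1 (8627) and at SPNCRNA.472, which lies 899 bp from bfr1, a brefeldin A efflux transporter gene (7606). Further ones were at SPNCRNA.3728, 189 bp from the proton pump gene pma1 (6845), and at SPNCRNA.1550, beside the glycolysis gene tdh1 (5761). The genes pma1 and tdh1 held untagged peaks with scores up to 963 and 697, against an untagged median of 129. These loci were therefore not free of untagged signal. Untagged scores were not looked up for the genes at or beside the other summits.

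Both tagged lists covered nearly the whole genome, and their maxima may follow the background measured in the untagged strain. Among regions with at least 2 untagged peaks, the summit lay in the highest-scoring of them in 27.1% of Pli1 regions (62 of 229; the highest 2.5% of random draws began at 5.68%) and in 31.8% of Nse2 regions (14 of 44; 6.82%). The remaining summits, such as that of Nse2 at rpp202, lay elsewhere in their regions. A different calibration factor or depth cannot be told apart from wide binding of the tagged proteins, because the lists hold 0 columns of read counts or factors. Wide binding of Pli1 and Nse2 stays open and was not tested.

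Repeated sequence cannot account for most Pli1 gaps, since 16.2% held a repeated 50-mer (49 of 302, interval 12.3 to 20.9%), though that exceeds the random median of 17 (10 to 25), and for Nse2 gaps the share was 47.7% (31 of 65, interval 35.1 to 60.5%; random median 5), but 29.8% away from the chromosome and rDNA ends (14 of 47, interval 17.3 to 44.9%), so it stays open at those ends. Low GC content may have added to the Pli1 gaps, whose mean was 29.2%, below the 35.5% that marks the lowest 2.5% of random draws, and those outside protein-coding genes had 70.8% AT, against 68.1% for random intergenic stretches (67.5 to 68.8%). Within the rRNA genes repeats cannot be told apart from other causes, because the share of repeated 50-mers differed by -0.632 percentage points between gaps (99.4%) and called sequence (100%), a measure with no room to differ. Whether reads shared with the budding yeast calibrator left the gaps in rRNA genes was not tested, because its genome was not at hand. At ura4 the tables argue against repeats or composition, with 0 repeated 50-mers and a GC content of 34.8% in the gap, above the 30.4% that marks the lowest 2.5% of windows. A candidate explanation is a deletion in both tagged strains of the HindIII fragment that holds ura4 (115346 to 117103), whose ends lay within 132 bp of the gap ends in both lists; the genotypes are not given in the sources used here, so this is a hypothesis.

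Pli1 summits at tRNA genes may reflect Pli1 at sites bound by TFIIIC, the RNA polymerase III factor that reads the B-box, which is a hypothesis. The B-box search could not test it at tRNA genes, because all 19 summits there had a B-box and no random positions were drawn for them. Away from tRNA, 5S and rDNA genes the tables argue against the B-box as a common mark of Pli1, since 7 of 105 Pli1 summits outside untagged peaks had a B-box within 150 bp (6.67%), against a random median of 6, with the highest 2.5% of draws from 10 up. A few true sites would stay within the random range, so the search cannot exclude them. Repeated sequence does not account for the summits outside untagged peaks as a whole, with 40 of 131 holding a repeated 50-mer within 150 bp (30.5%, interval 22.8 to 39.2%), though 18 of the 19 summits at tRNA genes and 10 of the 15 highest did. Background at tRNA genes below the untagged threshold cannot be told apart from Pli1 binding, because the Nse2 share at tRNA genes (3.23%, 2 of 62) has an interval that holds the Pli1 share of 6.35%.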
